A study of Bos taurus with 6 samples.

How the data were processed

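The material was longissimus dorsi muscle of 18 bulls of the Chinese Red Steppe breed, 9 aged 1 month and 9 aged 24 months. Per the labels, the tissue was taken at slaughter, frozen in liquid nitrogen and stored frozen. RNA was extracted with Trizol and purified on RNeasy columns, and amplified and labelled with biotin by the Affymetrix GeneChip procedure, per the labels' protocols. Total RNA of 3 bulls was mixed in each pool, and each of the 6 pools was hybridised to 1 bovine array of 24128 probe sets, 3 per age. The pools hold different bulls, so the p-values measure the spread between pools, and the spread between single bulls within a pool was not measured.

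Every array was assigned to its age from its label, and the columns of both tables were matched to samples by title. The main table, named for the program dChip, holds intensity values on a linear scale that the authors normalized across the arrays before they deposited them. The program's version, the probe model, and the background and normalization methods are not given in the sources used here. The same table holds a detection call (present, marginal or absent) for every probe set on all 6 arrays, and a detection p-value, as deposited by the authors, for the 3 arrays of 1 month. The method of the calls is not given in the sources used here. A second deposited table holds linear intensity values of the same arrays as the authors submitted them, with medians of 15.4 to 21.2 per array. Each of its columns correlates best with the column of the same title in the main table, and its scale and normalization remain unknown.

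Probe sets were named from the platform's gene annotation. Of the 24128 probe sets 13292 had 1 gene symbol, 86 had several and 10638 had none, besides 112 control probe sets. Through the gene identifier 13263 probe sets with 1 symbol matched the RefSeq gene table of the bovine assembly ARS-UCD2.0, and 0 symbols changed. Probe sets with several symbols were not named, and no coordinates were used.

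The main test used log2(intensity + 16). The log2 medians of the 6 arrays differed by 0.0303, under the limit of 0.2 set for a further normalization, so none was applied. Fold changes on this scale understate the change of dim probe sets. Control probe sets were left out, and a probe set was tested if it was called present on at least 3 of the 6 arrays, which kept 13204 and left out 10812. The coefficient for 24 months minus 1 month was fitted with limma 3.58.1 (lmFit and eBayes, no trend, not robust) in R 4.3.3, without covariates. P-values are two-sided and Benjamini-Hochberg adjusted over the 13204 probe sets, and a change is called at an adjusted p under 0.05. Every adjusted p for a gene comes from this limma fit or, where a setting is named, from the limma fit with that setting.

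Genes that were not called present on any array of an age have only a bound there. For them the brighter age's mean was set against the mean, over the dim arrays, of the higher of the probe set's own value and the lowest value called present on that array, and the result is given as at least that fold. For the genes named by rule the probe set's own value was the higher, so the bound equals the fitted fold. Such a bound concerns detection alone and leaves out the error of the fit. Where a gene had several probe sets, the named value is that of the probe set stated by the naming rule, and the range of the others is given where they differ.

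The 23 gene lists were written from textbook knowledge. Each list of at least 5 tested genes was compared with all other genes by limma's camera, two-sided, with the inter-gene correlation preset at 0.01 and the brightest tested probe set per gene, and adjusted over the 21 lists tested. The correlation was also estimated per list, and limma's fry, which asks whether the genes of a list move on balance one way without comparing them with other genes, was run beside it. For members of a list the adjusted p over all tested probe sets and the one adjusted over the list alone were counted on that probe set. Genes were named by rule: the 7 largest rises and the 7 largest falls among called probe sets with 1 gene symbol, all 3 arrays of an age above all 3 of the other and 1 probe set per gene (locus numbers passed over), and the 2 members of each list with the smallest p. Other members named beside a list count were chosen after their values were seen. The rule, the lists, the tests and most alternatives were fixed before the data were examined.

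Array quality was described by the share of present calls, the log2 ratio of 3' to 5' signal of actin and GAPDH, and the signal of the added controls, with two-sided exact permutation tests, for which 3 against 3 arrays allow no p under 0.1. The poly-A controls were added after seeing the data. Arrays have no read depth, and their number limits the precision.

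Alternatives fixed beforehand were quantile normalization, median centring, an offset of 1 or 50, no filter on dim probe sets, presence on all 3 arrays of an age, eBayes with trend and robust, array weights, an adjusted p of 0.01, a change of at least 2-fold, no probe sets of the cross-hybridising types, the second deposited table, the replicate number as a block, the mean of a gene's probe sets, and leaving out each array. The second table's log2 medians differed by 0.245, so it was quantile normalized by the same rule. Added after seeing the data were the actin ratio as a covariate, the second table without normalization, and the test of gene families by symbol.

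The fit was tested on simulated data of 13204 probe sets in which 200 were changed. Calls recovered 0%, 37.3% and 83.3% of changes of 0.5, 1 and 2 on the log2 scale, and 3.61% of calls were false. A ribosomal list shifted by -0.6 was called, and it was the 1 list called. The simulated probe sets were drawn independently, whereas the estimated correlation within the real ribosomal list was 0.59. False list calls that come from correlated genes could therefore not arise. Each probe set also had the same SD at both ages, and far fewer changed than the 2513 called in the real data, so these rates need not hold there. Figures were drawn with matplotlib 3.10.9 and pandas 2.3.3 in Python 3.11.15.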

Results

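Gene expression was measured in longissimus dorsi, the long loin muscle of the back, of Chinese Red Steppe bulls at 1 month and at 24 months of age, on an Affymetrix bovine array with 24128 probe sets. RNA of 18 bulls, 9 per age, was combined into pools of 3 bulls, and each pool was hybridised to its own array, so that n = 3 pools per age. The pools are numbered 1, 2 and 3 at 1 month and 2, 3 and 4 at 24 months. The comparison asks which genes differ in level between the muscle of calves and that of older bulls. Changes are given on the log2 scale as 24 months minus 1 month, and the value after each ± is the standard error of the limma fit unless it is marked SD. An array has no read depth, and the number of arrays limits the precision.

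Lists of slow fibre, fast fibre, glycogen and glycolysis, protein breakdown and antigen presentation genes stood higher in the older bulls, and lists of ribosomal, imprinted and foetal growth, collagen, other matrix and vessel genes stood lower. These were 10 of 21 lists tested by camera with a preset correlation, and 0 of them were called with an estimated correlation. Other splits of the 6 arrays, which mixed the ages, gave up to 11 lists with the preset correlation. Among the members of the 10 lists MYH7, the slow myosin heavy chain, rose by 1.13 ± 0.12 on its brightest probe set. IGF2, the foetal insulin-like growth factor, fell by 2.04 ± 0.20 (n = 3 pools per age). GRB10, the member with the smallest p in the list of IGF2, went the other way. It had no present call at 1 month and was at least 6.36-fold higher at 24 months. Of 13204 probe sets tested, 2513 changed with age: 1854 rose and 659 fell, so that 73.8% of the changes were rises. At least a 2-fold change was seen for 674 of the rises and 174 of the falls. The changed probe sets named 954 genes that rose and 405 that fell, with 3 genes in both directions through different probe sets. All 3 arrays of an age lay above all 3 of the other for 43.4% of tested probe sets, against 10% by chance. In the second table deposited by the authors, 1006 probe sets rose and 635 fell (61.3% rises) after quantile normalization, and 658 and 511 (56.3%) without it, an alternative added after seeing the data. With it, 1243 calls were shared with the 2513, 1241 of them in the same direction. Leaving out 24-month replicate 2, 3 or 4 brought the count of calls to 689, 586 and 526. Without 1-month replicate 1, 2 or 3 the count was 2626, 2293 and 3476. In all 6 fits with 1 array left out, 470 of the probe sets kept their call, 389 of them rises.

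The largest rise was that of FOS, a component of the AP-1 transcription factor, by 4.18 ± 0.29 (adjusted p = 0.00196). Next came ATP2A2, the calcium pump of slow muscle and heart (3.89 ± 0.24), SCN4B, a sodium channel subunit (3.69 ± 0.25), S100A1, a calcium-binding protein of striated muscle (3.44 ± 0.18), FBXO32, a ubiquitin ligase of muscle wasting (3.28 ± 0.85), NEB, the giant thin-filament protein nebulin (3.24 ± 0.19), and BOLA-DQB1, a class II histocompatibility chain (3.12 ± 0.73). The largest fall was that of HBB, the adult beta chain of haemoglobin, which was not called present on any 24-month array. It was at least 20.8-fold lower there, the error of the fit aside (-4.38 ± 1.02, 95% interval -6.80 to -1.96, adjusted p = 0.0291). HBG, a gamma-type haemoglobin chain, was at least 7.49-fold lower, the error of the fit aside, on a probe set with no present call at 24 months (-2.90 ± 0.81, adjusted p = 0.0480). Its brightest probe set, called present on 2 of the 3 24-month arrays, gave -2.54 ± 0.78 and did not pass (adjusted p = 0.0644). Both HBG probe sets are of a cross-hybridising type and carry the cluster number of the HBB probe sets. They therefore do not show a fall separate from that of HBB. INHA, the inhibin alpha subunit, fell by 2.74 ± 0.56. MGP, an inhibitor of calcification, fell by 2.38 ± 0.28, and S100A12, a neutrophil calcium-binding protein, fell by 2.37 ± 0.40. MEST, an imprinted gene, fell by 2.30 ± 0.63, and the transcription factor MYC fell by 2.28 ± 0.48. Other probe sets of these genes gave smaller changes: 3.86 for FOS, 3.25 for S100A1, 0.72 to 1.04 for ATP2A2, 0.54 and 2.57 for NEB, 0.87 to 1.60 for BOLA-DQB1, and -0.69 and -0.06 for MEST. The values of 0.72 for ATP2A2, 0.54 for NEB and -0.06 for MEST were those of their brightest probe sets. The other probe sets of FBXO32 and HBB did not pass: that of FBXO32 gave 2.48 ± 0.85 (adjusted p = 0.0839), and that of HBB, also without a present call at 24 months, a bound of 4.38-fold (adjusted p = 0.0717). FOS, ATP2A2, SCN4B, S100A1, NEB and MGP kept their calls whichever array was left out. FBXO32, HBB and HBG lost theirs in every such fit but the one without 1-month replicate 3, where the adjusted p were 0.000754, 2.74e-05 and 0.000812. INHA and MYC lost theirs without each 24-month array (adjusted p up to 0.0835 and 0.0862), as did BOLA-DQB1, also without 1-month replicate 1 (up to 0.111), and MEST, also without 1-month replicate 2 (up to 0.145), and S100A12 without 24-month replicates 3 and 4 (up to 0.0581). With the log2 actin ratio of 3' to 5' signal as a covariate, an alternative added after seeing the data, INHA gave -0.90 ± 0.89 (adjusted p = 0.559) and S100A12 -1.34 ± 0.73 (0.290), while FBXO32 (-0.68), HBB (0.10), HBG (0.34) and MEST (0.59) turned in sign, none of them called. With it MYC gave -3.83 and stayed called, while BOLA-DQB1 gave 4.93 ± 1.36 and was not called (0.0792); of the genes named by rule in the lists, CIDEA, LAMB1, ME1, MYH1, MYLK2, PIK3R1, PLOD1, PRELP and RGS5 also kept their direction but not their call (adjusted p from 0.0570 to 0.214).

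**Figure D1:**
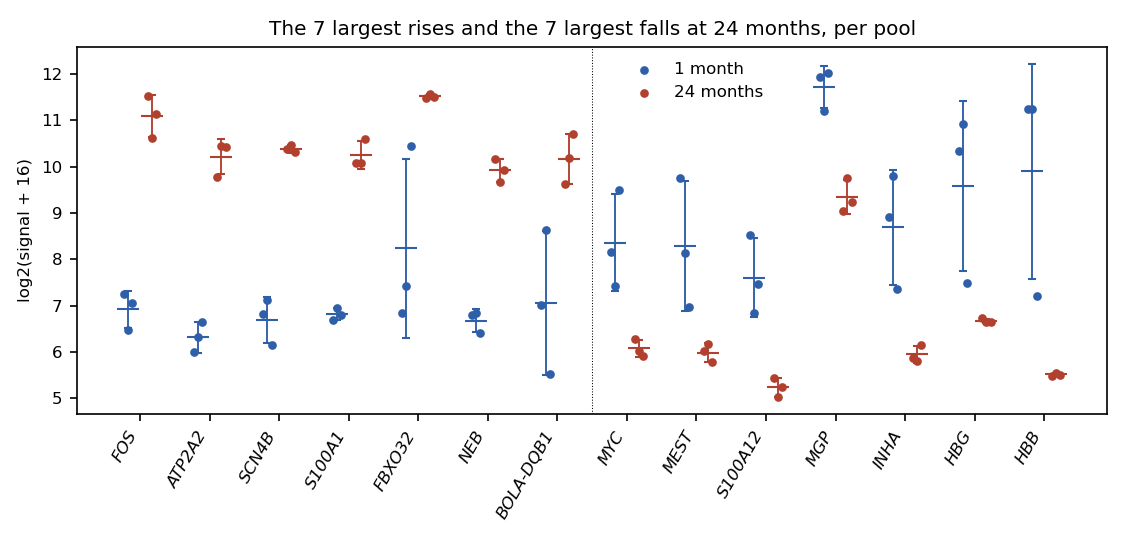
Signal of the 7 genes with the largest rises and the 7 with the largest falls, as log2(signal + 16), for 3 pools at 1 month (blue) and 3 pools at 24 months (red). Points are pools, the horizontal line is the mean and the bar is ± 1 SD; the 1-month pools of HBB, HBG and FBXO32 lie far apart (SD 2.32, 1.83 and 1.93), while their 24-month pools lie close together (SD 0.03, 0.04 and 0.05).

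Of the 23 gene lists fixed before the data were examined, 21 had at least 5 tested genes, and 10 of these stood apart from the other genes (camera with a preset correlation): 5 were higher and 5 lower at 24 months. With an estimated correlation camera called 0 lists, with 1 list at an unadjusted p under 0.05, and limma's fry called 5. The members named below beyond the 2 per list with the smallest p were chosen after their values were seen. The arrays of the ages also differed in quality: the log2 ratio of 3' to 5' signal of actin, which rises as RNA is degraded or labelled short, was 0.66 ± 0.20 (SD) at 1 month and 0.24 ± 0.02 (SD) at 24 months, and it was highest, at 0.85, in 1-month replicate 1. Over actin and GAPDH together the ages differed by -0.32 in this ratio, but by 0.21, in the opposite direction, in the second deposited table.

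The lists of slow and fast fibre genes stood higher in the older bulls. Of 11 tested slow fibre genes 5 rose (MYH7, TNNT1, PLN, ATP2A2 and FHL1) and 0 fell by limma, with 6 rises adjusted over the list alone; the median change was 0.45 (camera adjusted p = 0.00122, and adjusted p = 0.547 with an estimated correlation). MYH7 rose by 1.13 ± 0.12, from 11.95 to 13.07, and TNNT1, slow troponin T, by 0.83 ± 0.12. A dimmer MYH7 probe set gave 0.53 ± 0.32 and did not pass (adjusted p = 0.278). Of 9 fast fibre genes 3 rose (MYLK2, ACTN3 and TNNT3) and 0 fell, with 4 rises adjusted over the list alone; the median was 0.26 (adjusted p = 0.0235, and adjusted p = 0.547 with an estimated correlation). MYLK2, the skeletal myosin light chain kinase, rose by 1.60 ± 0.22. MYH1, a fast myosin heavy chain, rose by 3.03 ± 0.47 on its dimmest tested probe set, with a mean of 7.01 at 1 month. That call was lost without 24-month replicate 4 (0.0512). The 3 other MYH1 probe sets gave 0.12 to 0.92, and none of them passed (limma adjusted p from 0.0895 to 0.599). The fast fibre call was lost without 1-month replicate 3 (adjusted p = 0.0792), with quantile normalization (0.110) and with the actin covariate (0.128). On the brightest probe set of each gene, MYH7 and MYLK2 were the members of these lists that kept their calls whichever array was left out; the brightest ATP2A2 probe set lost its call without each 24-month array.

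The developmental sarcomere and junction list held 8 tested genes, of which 1 fell, also when adjusted over the list alone, and 0 rose by limma. ACTC1, the cardiac actin that foetal skeletal muscle also makes, fell by 1.22 ± 0.19 (adjusted p = 0.0086) and kept its call in all fits with 1 array left out; its fall was larger in the second deposited table (-4.21, and -4.37 without normalization) and with the actin covariate (-1.94). MYBPH, a myosin-binding protein of developing muscle, gave -1.38 ± 0.42 and did not pass (adjusted p = 0.0617). The list had a median of -0.32 and was not called (adjusted p = 0.152, and adjusted p = 0.576 with an estimated correlation), but it was called in the second deposited table (0.0240) and with the actin covariate (0.00694). Among 9 myogenic regulators and satellite cell genes 0 passed by limma, over all probe sets or adjusted over the list alone; MYF6, a regulator of late myogenesis, gave 0.82 ± 0.24 (adjusted p = 0.0556) and MEF2C 0.46 ± 0.14 (0.0611), and the list's median was 0.34 (adjusted p = 0.166, and adjusted p = 0.576 with an estimated correlation).

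The list of imprinted and foetal growth genes stood lower at 24 months, with 3 of 12 tested genes passing as falls and 1 as a rise. PEG10, an imprinted gene of retrotransposon origin, was not called present on any 24-month array and was at least 4.72-fold lower there (adjusted p = 0.00196). IGF2 fell by 2.04 ± 0.20 and PLAGL1, an imprinted zinc-finger regulator, by 1.46 ± 0.27. GRB10, an imprinted adaptor that restrains growth factor signalling, was not called present on any 1-month array and was at least 6.36-fold higher at 24 months (adjusted p = 0.000885). Adjusted over the list alone 1 rose and 4 fell; the median was -0.49 (adjusted p = 0.0173, and adjusted p = 0.576 with an estimated correlation). The calls of PEG10, IGF2 and GRB10 held whichever array was left out, and that of PLAGL1 was lost without each 24-month array. The list's call was lost without 1-month replicate 1 (0.0503), without the filter on dim probe sets (0.116), with fry (0.159) and with the actin covariate (0.859).

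In the list of IGF, insulin and growth hormone signalling, GHR, the growth hormone receptor, rose by 1.42 ± 0.22 and PIK3R1, the regulatory subunit of phosphoinositide kinase, by 0.98 ± 0.13. INSR, the insulin receptor, rose by 0.81 ± 0.21. These were the 3 rises among 20 tested genes, with 0 falls by limma; adjusted over the list alone 4 rose and 1 fell. The list was not called (adjusted p = 0.888, and adjusted p = 0.95 with an estimated correlation), and its median (0.07) and mean (-0.02) differed in sign. The call of GHR was lost without 24-month replicate 4 (0.0507), and another GHR probe set gave 0.28 ± 0.19. With the actin covariate GHR gave 0.63 ± 0.32 and was not called (0.253).

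Cell cycle genes went both ways. TPX2, a spindle assembly factor, rose by 1.14 ± 0.21 and TYMS, thymidylate synthase, by 0.68 ± 0.16, while STMN1, a microtubule regulator, fell by 0.99 ± 0.25 and PCNA, the sliding clamp of DNA replication, by 0.45 ± 0.11. Of 21 tested genes 2 rose and 2 fell, the same numbers as adjusted over the list alone. The list was not called (adjusted p = 0.888, and adjusted p = 0.95 with an estimated correlation), with a median of -0.01 and a mean of 0.02. All 4 calls were lost without each 24-month array, and with the actin covariate TPX2 gave 1.86 and TYMS 1.18.

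The list of glycogen and glycolysis genes stood higher at 24 months. PPP1R3C, which targets protein phosphatase to glycogen, rose by 2.96 ± 0.27 on its most changed probe set, with 2.34 and 1.63 on others. PFKM, muscle phosphofructokinase, rose by 2.88 ± 0.36, with 0.43 and 0.71 on its other probe sets. On the brightest probe set of each of 23 tested genes 4 rose (GPD1, PFKFB1, PGM1 and the glycogen phosphorylase PYGM) and 0 fell by limma, and 8 rose adjusted over the list alone. The list's median was 0.39 and 21 of the 23 genes were higher (adjusted p = 0.00122, and adjusted p = 0.576 with an estimated correlation). The call of the list held whichever array was left out, while the 4 single calls were lost without each 24-month array. With the actin covariate PFKM gave 1.26 ± 0.30 and was not called (0.0549).

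Few mitochondrial genes passed. In the TCA cycle and respiratory chain list 6 of 64 tested genes rose (UQCRC1, NDUFV1, DLAT, SDHA, NDUFS7 and NDUFA9) and 1 fell (COX8B, by 0.49 ± 0.12), but 0 passed adjusted over the list alone. Its median was 0.15 (adjusted p = 0.152, and adjusted p = 0.927 with an estimated correlation), and it was called without 1-month replicate 2 (0.00491) and without the filter on dim probe sets (0.0391). On the brightest probe set of each gene the rises numbered 10 without 1-month replicate 2 and 0 by limma without each 24-month array. DLAT, a subunit of pyruvate dehydrogenase, rose by 2.08 ± 0.27 on its most changed probe set, with 0.41 and 0.62 on its others. UQCRB, a complex III subunit, rose by 1.74 ± 0.16, with 0.02 on its brighter probe set. On these most changed probe sets both genes kept their calls whichever array was left out. Of 26 genes of fatty acid uptake and beta oxidation 1 rose and 0 fell by limma, and 0 passed adjusted over the list alone. UCP3, the uncoupling protein of muscle mitochondria, rose by 2.04 ± 0.44, a call lost without 1-month replicate 2 and without each 24-month array (adjusted p up to 0.0932); with the actin covariate UCP3 gave 0.13 ± 0.40 (0.869). ACADL, a long-chain acyl-CoA dehydrogenase, rose by 0.53 ± 0.14 on its dimmer probe set, a call lost without 1-month replicate 1 and each 24-month array (up to 0.164); with that covariate it gave 0.22 and DLAT 1.37, neither called. The beta oxidation list was not called (adjusted p = 0.888, and adjusted p = 0.95 with an estimated correlation); its median (0.04) and mean (0.05) lay above 0 while camera's direction was down, and with the actin covariate it was called as lower (0.0416).

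Several genes of fat cells and of fat synthesis rose, without a call for either list. AGPAT2, an enzyme of triglyceride synthesis, was not called present on any 1-month array and was at least 2.10-fold higher at 24 months, and CIDEA, a lipid droplet protein, was at least 1.66-fold higher by the same measure. THRSP, a regulator of fat synthesis, rose, as did DGAT2, an enzyme of triglyceride synthesis, by 1.21 ± 0.32 and CFD, the adipocyte protease adipsin, by 0.92 ± 0.26. These were the 5 rises among 13 adipocyte genes, with 0 falls by limma and 5 rises adjusted over the list alone; the median was 0.65 (adjusted p = 0.123, and adjusted p = 0.576 with an estimated correlation). The adipocyte list was called without 1-month replicate 1 (0.0138, with 7 rises), in the second deposited table (0.0240) and with the actin covariate (0.0398). Its mean was 7.42 in 1-month replicate 1, within the 7.23 to 7.55 of the 24-month pools. In 1-month replicates 2 and 3 the mean was 6.48 and 6.71. Of 12 genes of fatty acid and triglyceride synthesis 3 rose (GPAM, ME1 and SREBF1) and 0 fell, and 3 rose adjusted over the list alone, with a median of 0.38 (adjusted p = 0.218, and adjusted p = 0.576 with an estimated correlation). GPAM, which starts glycerolipid synthesis, rose by 1.47 ± 0.37 and ME1, malic enzyme, by 1.31 ± 0.18. AGPAT2 and ME1 kept their calls whichever array was left out, but with the actin covariate neither was called (0.69 ± 0.24 and 0.93 ± 0.33, adjusted p = 0.132 and 0.135), while GPAM gave 3.08. CIDEA lost its call without each 24-month array (up to 0.0757), and GPAM also without 1-month replicate 2 (up to 0.128).

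The list of ribosomal protein and translation factor genes stood lower at 24 months. Of 65 tested genes of the list 32 fell and 0 rose by limma, and 49 fell adjusted over the list alone; 63 of the 65 were lower at 24 months. The median was -0.47 (adjusted p = 2.23e-18, and adjusted p = 0.576 with an estimated correlation). The mean of the list was 12.37, 12.15 and 12.38 in the 1-month pools and 11.83, 11.83 and 11.78 in the 24-month pools. RPL10A fell by 1.21 ± 0.14 and RPL3 by 1.29 ± 0.18. RPS7 was at least 2.46-fold lower on a dim probe set that was not called present on any 24-month array, fell by 0.71 ± 0.14 on its brightest and gave 0.21 on another. In the second deposited table without normalization RPL10A gave -1.83. The list kept its call in all 6 fits with 1 array left out, while the single falls numbered 5, 6 and 3 without 24-month replicates 2, 3 and 4; RPL3, RPL10A and RPL14 kept theirs in all 6 fits. With the actin covariate the list kept its call (4.12e-10) and had a median of -0.48, while 2 single falls passed, as the median standard error of the members was 0.256 against 0.128.

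The list of protein breakdown genes stood higher at 24 months, with 7 of 27 tested genes rising. CAPN3, the muscle calpain, rose by 1.73 ± 0.21 and FOXO4, a transcription factor of the atrophy programme, by 1.30 ± 0.15. Cathepsin D (CTSD), the proteasome subunits PSMC1, PSMD4 and PSMD11, and the autophagy receptor SQSTM1 rose by 0.60 to 0.91. CTSV, a lysosomal cathepsin, fell by 0.72 ± 0.20. In all 7 rose and 1 fell, and 10 and 2 adjusted over the list alone; the median was 0.37 (adjusted p = 0.0173, and adjusted p = 0.547 with an estimated correlation). CAPN3 and FOXO4 kept their calls whichever array was left out, and the other single calls of the list did not. The rises numbered 2 without each 24-month array and 11 without 1-month replicate 3. In the second deposited table CAPN3 gave 1.01 and was not called (0.104), and FOXO4 gave 0.84 and was not called (0.0529) without normalization of that table. With the actin covariate the list was not called (0.572), and FBXO32 gave -0.68.

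Matrix genes were lower at 24 months as lists, with few single genes passing. ELN, elastin, fell by 1.89 ± 0.37, and the basement membrane genes NID2, LAMB1 and LAMC1 fell by 1.45 ± 0.29, 1.36 ± 0.21 and 0.88 ± 0.23. EFEMP1, a fibulin, rose by 0.59 ± 0.15. Of 30 other matrix glycoproteins and proteoglycans 1 rose and 4 fell, the same numbers as adjusted over the list alone, with a median of -0.57 (adjusted p = 0.00122, and adjusted p = 0.576 with an estimated correlation). PRELP, a small proteoglycan, fell by 0.91 ± 0.12 on a dim probe set and gave -0.10 ± 0.53 on the brighter. Of 21 collagens and collagen processing genes COL4A1, a basement membrane collagen, fell by 0.99 ± 0.23 and PLOD1, a lysyl hydroxylase, rose by 0.51 ± 0.14, with 0 passing adjusted over the list alone; other probe sets of both gave the opposite sign (0.19 and -0.58). With the actin covariate COL4A1 gave -1.87, and in the second deposited table PLOD1 gave 0.34 and was not called (0.263). The collagen median was -0.77 (adjusted p = 0.00669, and adjusted p = 0.576 with an estimated correlation). The mean of the collagen list was 9.47, 8.24 and 8.20 in 1-month replicates 1, 2 and 3, against 7.91, 8.0 and 7.85 at 24 months, and that of the other matrix list was 9.57, 8.07 and 8.53 against 8.07, 8.18 and 8.06. Replicate 1, the highest pool for both, was also the array with the highest actin ratio; without it the shifts relative to other genes moved from -0.76 to -0.38 and from -0.66 to -0.28, and with the actin covariate they turned to 0.42 and 0.23. Both calls were lost with fry (0.244 for each). On the brightest probe set of each gene, 0 of the single calls of these lists held in all limma fits with 1 array left out. Without 24-month replicates 2, 3 and 4 the other matrix list had 1, 0 and 0 falls on these probe sets, and the collagen list 0. The dim PRELP probe set kept its call in all these fits.

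**Figure D2:**
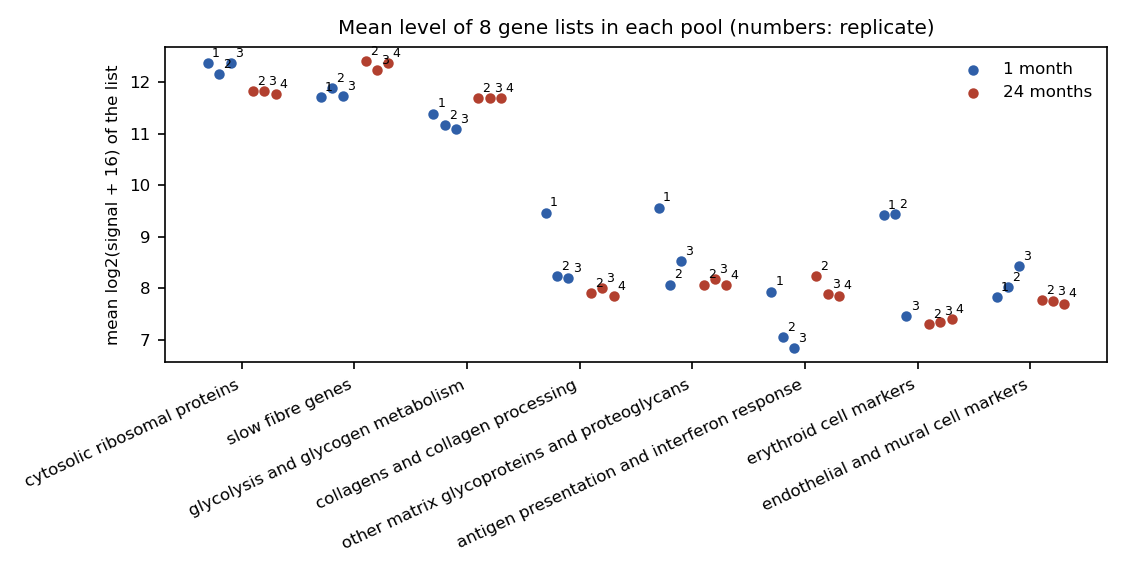
Mean log2(signal + 16) of the tested members of 8 gene lists in each pool, with 1-month pools in blue, 24-month pools in red and the replicate number beside each point. In the 2 matrix lists 1-month replicate 1 lies apart at 9.47 and 9.57, while the ribosomal list separates the ages in every pool.

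Markers of fibroblasts and tendon cells were not called as a list. THY1, a surface protein of fibroblasts and other cells, rose by 1.07 ± 0.15 in all fits with 1 array left out. It was the 1 rise among 12 tested markers, with 0 falls by limma and 1 rise adjusted over the list alone, and PDGFRA gave -0.50 ± 0.19 (adjusted p = 0.109). The list was not called (adjusted p = 0.888, and adjusted p = 0.95 with an estimated correlation), with a median of 0.06 and a mean of -0.03; its mean was 8.45 in 1-month replicate 1 and 7.28 to 7.86 in the other pools.

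The list of endothelial and mural cell markers stood lower at 24 months, with 4 of 14 tested markers falling. RGS5, a pericyte gene, fell by 0.93 ± 0.25, TEK, the angiopoietin receptor, by 0.80 ± 0.18, PECAM1 by 0.70 ± 0.19 and RAMP2 by 0.56 ± 0.15. There were 0 rises by limma, and 4 falls adjusted over the list alone; the median was -0.41 (adjusted p = 0.0300, and adjusted p = 0.576 with an estimated correlation). The list's call was lost without 1-month replicate 2 (0.0550) or 3 (0.122), without the filter on dim probe sets (0.0542) and with fry (0.182), and the 4 single calls were lost without each 24-month array. Without 1-month replicate 3 the shift relative to other genes moved from -0.40 to -0.22, and with the actin covariate to -1.13, where the list kept its call (0.000161) with 5 falls, and RGS5 gave -1.60 and TEK -1.39. The 4 nerve and Schwann cell markers tested gave 0 passing by limma, over all probe sets or adjusted over the list alone, and a median of 0.22. MBP, the myelin basic protein, gave 0.42 ± 0.13 (adjusted p = 0.0647), and CNP, another myelin protein, 0.16 ± 0.21 on its brightest probe set (0.619). The CNP probe set named by the rule had no present call at 1 month. It gave a bound of 1.25-fold higher, the error of the fit aside (0.32 ± 0.18, adjusted p = 0.259).

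The list of antigen presentation and interferon genes stood higher at 24 months, with 8 of 21 tested genes rising. BOLA, a class I histocompatibility chain, rose by 1.38 ± 0.19, from 10.83 to 12.21. The class II genes BOLA-DRB3, BOLA-DRA, BOLA-DMB and BOLA-DMA rose by 1.95 ± 0.50, 1.77 ± 0.49, 1.55 ± 0.25 and 1.11 ± 0.24, and the peptide loading genes TAP1 and TAPBP by 0.94 ± 0.24 and 0.44 ± 0.12. CXCL10, an interferon-induced chemokine, was not called present on any 1-month array and was at least 2.63-fold higher at 24 months. Its size depended on the offset: the fitted change of 1.40 became 2.19 with an offset of 1 and 0.80 with 50, called in each. By limma 0 fell, and 8 rose adjusted over the list alone; the median was 0.66 (adjusted p = 0.00316, and adjusted p = 0.576 with an estimated correlation). The call was lost with fry (0.106), and with the actin covariate the shift relative to other genes moved from 0.68 to 1.76. The pools of 1 month differed here too, with list means of 7.93, 7.06 and 6.84 against 8.24, 7.88 and 7.86, and the single rises ranged from 2 to 12 as 1 array was left out.

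The list of immune cell markers was not called. Among its members the neutrophil genes S100A12 and S100A8 fell by 2.37 ± 0.40 and 1.87 ± 0.37, and S100A9 was at least 2.56-fold lower, with no present call at 24 months. ITGB2, the leukocyte integrin beta chain, rose by 0.73 ± 0.19 and CORO1A, a leukocyte actin regulator, by 0.55 ± 0.15. Of 22 tested markers 2 rose and 3 fell, also adjusted over the list alone (adjusted p = 0.738 for the list, and adjusted p = 0.95 with an estimated correlation); its median was 0.22 and its mean -0.01. All 5 calls were lost in at least 1 fit with an array left out, and with the actin covariate the list rose (shift 0.57, adjusted p = 0.00310) while S100A8 gave -1.02 ± 0.72 (0.408), against -2.84 in the second deposited table. Of the 4 erythroid markers tested HBB passed, and 2 rose and 2 fell adjusted over the list alone; AHSP and GYPC gave 0.45 ± 0.14 and 0.76 ± 0.23 (adjusted p = 0.0687 and 0.0590). The HBB signal was 11.24, 11.24 and 7.21 in 1-month replicates 1, 2 and 3. The erythroid and nerve lists, with 4 genes each, were not tested as lists; the erythroid median was -1.05.

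Stress and immediate early genes moved apart. FOS, JUN, EGR1, IER2 and DUSP1, which are induced within minutes of a stimulus, were higher at 24 months: JUN, the partner of FOS, rose by 2.81 ± 0.21 on its most changed probe set, EGR1 by 1.64 ± 0.33 and DUSP1 by 0.99 ± 0.12. HMOX1, HSPB8 and SOD2 rose by 0.81 to 1.38. MYC fell by 2.28 ± 0.48, GADD45B, a stress-induced growth arrest gene, by 1.28 ± 0.30 and the heat shock protein HSPH1 by 0.98 ± 0.20. On the brightest probe set of each of 27 tested genes 7 rose and 3 fell, and 10 and 3 adjusted over the list alone, JUN not among the 7; the median was 0.40 and the list was not called (adjusted p = 0.141, and adjusted p = 0.576 with an estimated correlation), though it was called in the second deposited table (0.0315) and without the filter on dim probe sets (0.0449). FOS, DUSP1 and HSPB8 kept their calls whichever array was left out; other JUN probe sets gave 0.73 to 1.84.

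**Figure D3:**
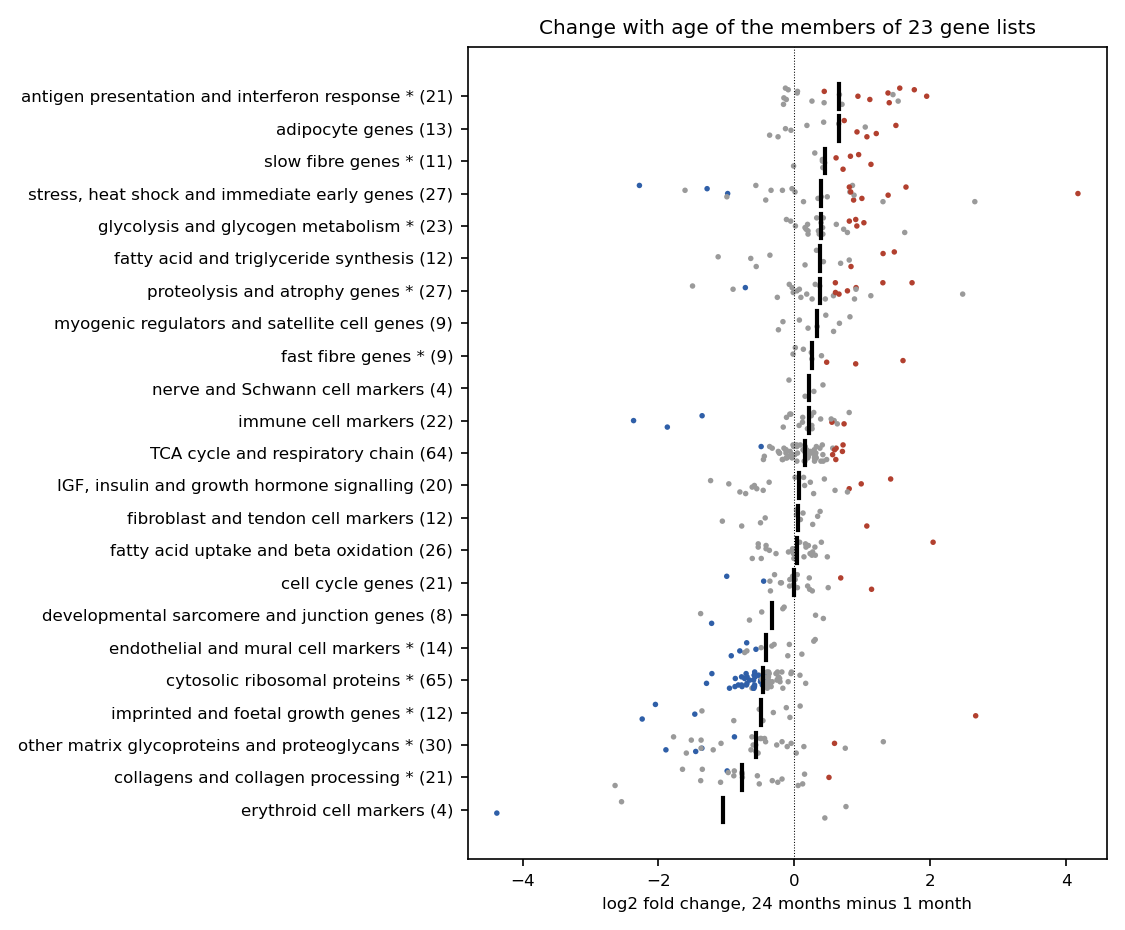
Change with age (log2, 24 months minus 1 month) of each tested member of 23 gene lists, with the number tested in brackets. Red points rose and blue points fell at an adjusted p under 0.05, grey points did not pass, black bars are list medians and a star marks the 10 lists called with a preset correlation; none of them was called with an estimated correlation.

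The arrays themselves differed between the ages in the controls as well as in the genes. The share of probe sets called present was 50.3% ± 1.88 (SD, n = 3) at 1 month and 55.4% ± 0.85 (SD, n = 3) at 24 months. The log2 ratio of 3' to 5' signal of GAPDH was 0.33 ± 0.07 (SD) and 0.11 ± 0.03 (SD). The poly-A control transcripts, bacterial RNAs that carry a poly-A tail and are added to the sample before labelling, had a mean signal of 7.28 ± 0.28 (SD) and 9.38 ± 0.37 (SD), 4.28-fold higher at 24 months, and their own ratio of 3' to 5' signal was 1.95 ± 0.25 (SD) and 1.2 ± 0.12 (SD). The hybridisation controls, which are added after labelling, had 9.86 ± 0.10 (SD) and 9.65 ± 0.22 (SD). For the first 5 of these 6 measures, actin included, all arrays of an age lay on the same side, which gave p = 0.1 in a two-sided exact permutation test (0.12 after Benjamini-Hochberg over the 6 tests), the smallest p that 3 against 3 arrays allow; the hybridisation controls gave an exact p of 0.3. Across tested probe sets, the 24-month arrays correlated with one another at r = 0.985 to 0.989 and the 1-month arrays at 0.903 to 0.934, against 0.870 to 0.916 between the ages. These correlations are across genes, which are not independent replicates. The median SD of a probe set was 0.26 at 1 month and 0.12 at 24 months, and it was larger at 1 month for 80.6% of probe sets. The first principal component, with 56.3% of the variance, separated the ages, and the next, with 23.2%, spread the 1-month pools.

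**Figure D4:**
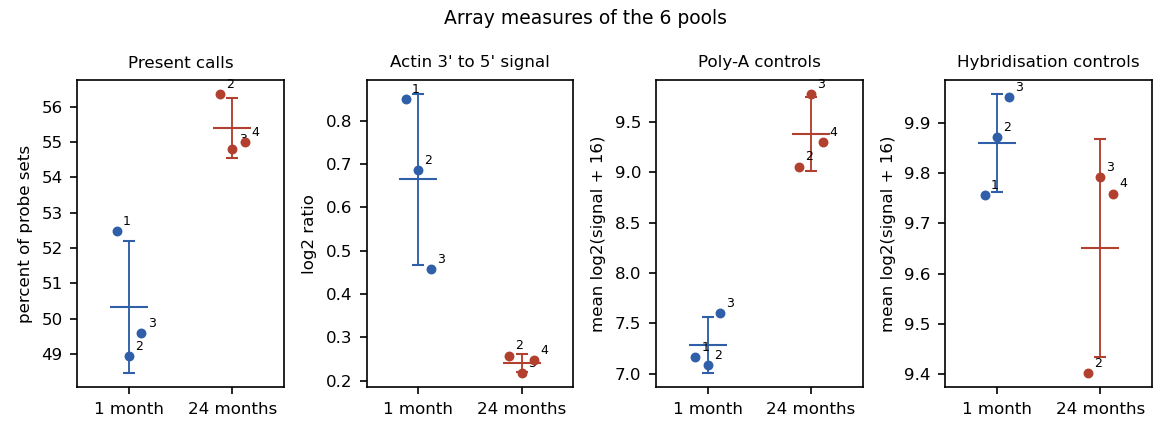
Present calls in percent, log2 ratio of 3' to 5' signal of actin, mean log2(signal + 16) of the poly-A controls and of the hybridisation controls for each of the 6 arrays, numbered by replicate, with the mean and ± 1 SD per age. The ages do not overlap in the first 3 panels; the poly-A controls lie at 7.08 to 7.60 at 1 month and at 9.06 to 9.78 at 24 months.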

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

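The tests of the labelling difference, of blood and of short transcripts, the poly-A controls, the actin covariate and the choice of a gene's dimmest against its brightest probe set were made only after results were seen, as was the reading of the blood test as undecided.

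The added poly-A controls stand outside the gene comparison, and their signal differed between the ages: it was higher at 24 months by 2.10 on the log2 scale, with 1.90 to 2.26 as each array was left out. Beside this, 73.8% of the 2513 calls were rises. The tables argue against normalization between arrays as the whole cause of that excess, since 64.8% of calls were rises with quantile normalization. Median centring gave 73.4%, but it could change little, as the log2 medians of the arrays differed by 0.0303. The second deposited table gave 61.3%, and 56.3% without normalization, so that part of the excess may rest on scaling. A loss of dim probe sets on the 1-month arrays is argued against as the whole cause by the brighter probe sets, where 73.2% of calls were rises, against 74.7% among the dimmer. Part of the excess may still lie there, as 64.7% of calls were rises without the filter on dim probe sets. In the main fit 175 called probe sets had no present call at 1 month, against 21 at 24 months. The controls' own log2 ratio of 3' to 5' signal was 1.72 to 2.21 at 1 month and 1.08 to 1.32 at 24 months. These controls are added RNA, so this argues that processing also differed between the ages. How the calls divide between labelling and age cannot be told, as labelling and age go together. A smaller share of poly-A RNA in older muscle stays open and untested for the controls' signal. Of the 10 splits of the 6 arrays, too few to give a share under 0.05, 1 gave as many calls, the real one with 2513. The highest other gave 0 by limma (88 to 324 at an unadjusted p under 0.05).

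Probe sets of 1 gene often changed by different amounts, with a gap of over 1 log2 unit between the dimmest and the brightest in 111 of 1420 genes. Signal lost toward the 5' end of transcripts on the 1-month arrays is a candidate explanation: across genes, which are not independent replicates, the gap in the difference between the 24-month arrays and 1-month replicate 2 alone, an arm of 1 pool, went with the gap between the 1-month arrays of lowest and highest actin ratio at r = 0.337 (95% bootstrap interval 0.273 to 0.400, Spearman's rho 0.340). The ratio of 3' to 5' signal itself differed in the opposite direction in the second table (0.21 against -0.32), so this rests on the main table. No probe positions were used and the pairs were ordered by brightness, so the correlation cannot tell loss at the 5' end from other differences between probe sets. Over all tested probe sets, without pairing, the same differences between arrays correlated at r = 0.191. Compression of bright signals stays undecided. Among 494 genes with a mean fall the dimmer probe set fell by less than the brighter (median difference of sizes -0.0867, interval -0.116 to -0.059). Among 926 genes with a mean rise the dimmer probe set rose by more (0.140). Over all pairs the dimmer probe set moved up against the brighter by a median of 0.176. Such a shift can hide compression among the falls, so the falls cannot decide the question. Transcript forms that change with age were not tested and stay open.

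The list of ribosomal proteins and translation factors was lower by a median of -0.47 over 65 genes. Normalization is argued against as the whole cause, as relative to all genes the list kept a median of at most -0.476 with quantile normalization. Median centring shifts all genes of an array alike, so it could not move this value and tests nothing here. Better labelling of short transcripts on the 1-month arrays stays open: 73 respiratory chain subunits had a median of -0.05, higher by 0.415 with an interquartile range of 0.369, but no transcript lengths were used. Of 19 genes with COX symbols 5 fell, with a median of -0.16. Over the scalings, the actin covariate and leaving out each array, their median ran from -0.29 to -0.03, with 1 to 6 falls and at most 1 rise. The labelling difference stays open as a cause, and so does age. With the actin covariate, which itself separates the ages, the median was -0.48 and the list kept its call (adjusted p = 4.12e-10), while 2 single falls were called as the median standard error went from 0.128 to 0.256.

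Of the 10 splits of the arrays, too few to give a share under 0.05, 3 gave at least as many gene lists as the real one, the real one with 10 included, and the highest other gave 11. The count of lists thus does not tell the real split from the others. The S100A8 signal minus that of HBB was -2.46, -3.96 and 0.71 on the log2 scale in 1-month replicates 1, 2 and 3, a range of 4.67, and of 1.49 without replicate 3.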

How the results depend on the processing

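The actin covariate, the second deposited table without normalization, and some settings of the quality measures were added after seeing the data. Counts of calls stayed within 1.5 times the main ones (2513 calls, 1854 rises, 659 falls) with quantile normalization (2368, of which 2156 were shared with the 2513), median centring (2444), offsets of 1 (2470) and 50 (2461), trend and robust (2568), array weights (2770), presence on all 3 arrays of an age (2473) and without the cross-hybridising types (2285). Without the filter on dim probe sets 1269 fell, and 3 lists were lower. An adjusted p of 0.01 left 591 calls (486 and 105), and a 2-fold minimum 848 (674 and 174), by construction. The second table gave 1641 calls with 1006 rises, and 1169 with 658 rises without normalization, where the median of all tested probe sets moved from 0.06 to -0.07. The actin covariate gave 996 calls (655 and 341), of which 418 were shared with the 2513; it separates the ages, so it also takes up age. As each array was left out, calls ranged from 526 to 3476, rises from 432 to 2451, falls from 94 to 1025 and lists called from 8 to 10. Without 24-month replicates 2, 3 and 4 the ribosomal list kept median changes of -0.48, -0.46 and -0.46, near its main -0.47. Its median standard error went from 0.128 to 0.162, 0.163 and 0.167. Single calls of that list were thus lost with a larger error and not with a smaller change. The median SD of a probe set was 0.26 at 1 month and 0.12 at 24 months. For the other settings, the thresholds aside, the cause was not tested.

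With the replicate block 129 probe sets were called (114 and 15, 121 of them shared with the 2513; 3115 at an unadjusted p under 0.05). Replicate numbers 2 and 3 occur at both ages, but the pools are of different bulls, and deviations of same-numbered arrays correlated at r = -0.18 and 0.04, so the numbers pair nothing. The other replicate numbers occur at 1 age each, so the block takes up those arrays. The age effect with the block thus comes from replicates 2 and 3 alone, and is no check over all arrays. In that fit the 10 lists kept their calls, and the adipocyte (0.00158) and developmental sarcomere (0.025) lists were called too. With an estimated correlation camera called 0 lists, 0 higher and 0 lower (adjusted p 0.547 to 0.95, 1 list at an unadjusted p under 0.05), and fry called 5, with 1 lower. The difference in 3' to 5' signal, -0.32, was -0.21 with quantile normalization and 0.21 in the second table, and the cause was not tested. The poly-A difference, the present-call difference (1212 probe sets, 1045 to 1469 as each array was left out) and the correlation gap (0.059) stayed within their spread.

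Over the 55 named genes, other settings gave 607 values on the same side of the threshold, 86 that lost and 8 that gained it and 8 that reversed; with an array left out these were 253, 75, 2 and 0. Over single lists they were 180, 21, 9 and 21, and 115, 4, 2 and 5. The reversed values, as log2 changes of genes and shifts of lists relative to other genes, were as follows, and their cause was not tested; the sign of the shift was taken for a list's direction after the results were seen, because camera's direction can differ from it. Cell cycle genes (main -0.02) gave 0.012 with quantile normalization, 0.0085 without the filter and 0.090 with the actin covariate. Beta oxidation (0.01) gave -0.039 with quantile normalization, -0.000615 with offset 1, -0.00437 without the filter, -0.027 in the second table, -0.13 with the block, -0.010 with the mean of probe sets and -0.48 with the covariate. Immune cell markers (-0.05) gave 0.00136, 0.00709, 0.10 and 0.12 with quantile normalization, without the filter, in the second table and with the block, and 0.57 with the covariate. IGF signalling (-0.06) gave 0.055 in the second table, and fibroblast markers (-0.07) 0.28 with the block and 0.70 with the covariate. With the covariate the collagens gave 0.42, other matrix genes 0.23, stress genes -0.087, CNP -0.16, FBXO32 -0.68, HBB 0.0987, HBG 0.34, MEST 0.59 and MYF6 -0.034. MBP gave -0.19 in the second table and -0.24 without normalization. As each array was left out, the shift ranged from -0.13 to 0.11 for beta oxidation, -0.18 to 0.12 for immune markers, -0.28 to 0.24 for fibroblast markers, -0.071 to 0.027 for the cell cycle and -0.11 to 0.0091 for IGF signalling. Signal over background limits the rest: 436 tested probe sets were not called present on any 1-month array and 78 on any 24-month array.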

Other observations

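The test of gene families by symbol was chosen only after the results were seen.

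The ASB family, which codes for substrate receptors of ubiquitin ligases with ankyrin repeats, had 9 tested genes, of which 5 rose and 0 fell by limma, with a median change of 1.07: ASB15 rose by 1.98 ± 0.36, ASB2 by 1.94 ± 0.14, ASB8 by 1.47 ± 0.22, ASB11 by 1.07 ± 0.20 and ASB12 by 0.97 ± 0.24 (camera adjusted p = 0.0150, and adjusted p = 0.671 with an estimated correlation). The other 4 did not pass: ASB5 gave 1.09, ASB3 0.48, ASB7 0.06 and ASB13 -0.09. Over quantile normalization, median centring, the second deposited table with and without normalization, the actin covariate and leaving out each array, the median ranged from 0.59 to 1.13 and the rises from 2 to 6. Of 11 autophagy genes with ATG symbols 4 rose and 0 fell: ATG4A by 1.07, ATG4D by 0.97, and ATG101 and ATG9A by 0.63 each. Their median was 0.52, with 0.23 to 0.61 over the same settings and 1 to 7 rises (adjusted p = 0.0202, and adjusted p = 0.671 with an estimated correlation).

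Among kinesin motor genes with KIF symbols, 10 were tested, and KIF22 and KIF1C rose by 1.61 and 0.71. The family median was 0.48 (adjusted p = 0.0310, and adjusted p = 0.671 with an estimated correlation), with 0.14 to 0.67 over the same settings, 0 to 4 rises and at most 1 fall. Symbols beginning with RPL and RPS were called as well, the latter including S6 kinases such as RPS6KB1 and the binding protein RPS19BP1, which are not ribosomal subunits: 27 of 40 RPL symbols fell with a median of -0.58, and 7 of 31 RPS symbols with a median of -0.35 (adjusted p = 0.671 and 0.836 with an estimated correlation). Over the same settings the RPL median ran from -1.05 to -0.51 and the RPS median from -0.79 to -0.28, with 5 to 30 RPL falls and 0 to 13 RPS falls, and at most 1 RPS rise. These were the 5 families called of 82 tested with a preset correlation, and camera with an estimated correlation called 0, with 2 at an unadjusted p under 0.05.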
